A study of Homo sapiens with 8 samples.

How the data were processed

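Nuclei of peripheral blood mononuclear cells from people with multiple myeloma were profiled with a multiome assay, which reads RNA and open chromatin from the same nucleus. Per the labels, thawed cells received DMSO or mezigdomide at 1 nM for 1 hour and were then stimulated for 3 days with beads that engage CD3 and CD28. Mezigdomide is a cereblon modulator that directs the Ikaros-family proteins IKZF1 and IKZF3 to degradation. The 8 samples carry 4 label numbers, each with a DMSO and a mezigdomide sample. The label numbers are written here as pairs A, B, C and D and were taken as donors. The labels also give "T-cell" and "cell line" as the source, while the protocol describes blood mononuclear cells, so cell classes were read from the RNA. A count matrix was used for 7 libraries, 4 with DMSO and 3 with mezigdomide; the mezigdomide sample of pair D, with 17445 barcodes, was not analysed here. Nothing in the labels says whether any sample was processed on the same day as another.

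The deposited matrices hold raw counts, whole numbers per feature and barcode, as the file headers and the values show: unique molecular identifiers (UMIs) for 36601 genes, and counts for peaks of open chromatin. The deposited barcode and feature files hold text (unit other). The authors used Cell Ranger with GRCh38. Its version and settings are not given in the sources used here. Peaks differ in number and place between libraries, which shows that they were called in each library on its own. The feature line of 1 peak of a mezigdomide library was blank and that peak was left out.

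Total UMIs ran from 1827506 in the DMSO library of pair A to 42380266 in the DMSO library of pair B. Nuclei with at least 500 UMIs and 250 genes and at most 20% mitochondrial UMIs were kept, which left 20668 of 25460 barcodes. An automatic doublet call marked 53 of them, or 0.256%, too few for the loading. The highest doublet scores were therefore removed at 0.8% per 1000 barcodes, 801 nuclei in all, a rule set after that result was seen. The 19867 nuclei left were clustered with scanpy 1.11.5 and igraph 0.11.9 under Python 3.11.15 (2000 variable genes, 30 components, 20 neighbours, Leiden resolution 1, seed 1). Before that, the libraries were aligned in the component space by a scheme like that of Harmony. It penalises groups of nuclei from a single library and regresses the library out within each group. Each library has a single treatment, so this also draws DMSO and mezigdomide nuclei into common clusters. Clustering without it was not run. Clusters were named from marker genes fixed before the data were examined. The limits used with them, namely the ratio of CD8 to CD4 transcripts that separates these classes and the rule that leaves a cluster with 2 or more ribosomal protein genes among its leading genes unnamed, were set after the clusters were seen. CD4, CD8, regulatory and unresolved T clusters together form the T-cell-like class, with 14104 nuclei. The 115 genes that carry information on sex were left out of every sum and test.

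Counts were summed over the nuclei of a class in each library with at least 20 such nuclei, and the library was the replicate. Groups were compared with the quasi-likelihood test of edgeR 4.0.16 under R 4.3.3, with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors derived from the test, as the change divided by the square root of its F statistic. Errors of levels are SDs between libraries. Levels are given in CPM (counts scaled to library size), for RNA with TMM scaling. A difference of effect between CD8 and CD4 T-like nuclei was tested as an interaction with the library as a block. Promoter counts were the sum of peaks within 2 kb of the annotated start of a gene, for genes with such a peak in every library. After the promoter calls were seen, 3 settings were added: the covered length of the peaks as an offset, only peaks in stretches of overlapping peaks that hold a peak of every compared library, and both. Start positions came from GENCODE 29 on GRCh38 instead of the feature files, a change from the plan; 1985 gene IDs were not in that annotation. The 29 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01. Shares of nuclei were compared by exact permutation tests, which for 4 against 3 libraries cannot give a two-sided p under 0.0571. Other software was DESeq2 1.42.0, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

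The rule for named genes was fixed before the data were examined. It takes IKZF1, IKZF3, IKZF2, ZFP91 and CRBN always, the 10 called genes per direction with the smallest p that moved the same way in every pair, up to 4 members of each list by p, and 5 called genes per direction in the other comparisons. Immunoglobulin and T-cell receptor segments, genes whose presence differs between people and genes with clone-based names were not named. Because no gene was called with all 7 libraries, the second part of the rule named no gene there. It was applied again without pair A, asking for the same direction in pairs B and C; as the rule says, the 4 lower genes missing from the 10 came from the fit with the label number as a block. Of each list the text names at most the first member by p with all libraries and the first 2 elsewhere.

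Several analyses were chosen after the data were seen: the fits without pair A, which were prompted by that pair running against the others; the fits without pair B and without pair C, run for comparison; the fits of B-like clusters 9 and 10; and the fit of NK-like nuclei, for which 0 of 5985 genes were called by edgeR with all libraries that had 20 such nuclei (419 at an unadjusted p under 0.05; 1 by DESeq2; 138 of 20171 without the low-count filter) and 48 without pair A. With the number as a block and pair A absent, 369 genes were called in NK-like nuclei. Across genes, deviations of same-numbered libraries from their group means correlated at 0.06 in pair A, 0.64 in pair B and 0.04 in pair C. The pair A libraries were counted in the group means. Crossing pairs A and C gave higher values, 0.319 for DMSO of A with mezigdomide of C and 0.218 for the reverse. The other crossed values were negative, from -0.440 to -0.259. This check therefore does not settle whether the libraries of pairs A and C are paired. The pairing, on which the block fits rest, was taken from the labels. Other settings, chosen before the data were examined, were the label number as a block, each library left out in turn, another scaling, no filter on low counts, DESeq2, voom with sample weights, all nuclei, equal numbers of nuclei, doublets kept, stricter filters, a lower clustering resolution, gates on CD4 and CD8 transcripts, other list tests and a 1 kb promoter window.

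The tests were checked on simulated data of the same design with 200 changed genes. For the difference between CD8 and CD4, the CD4 and CD8 sums of a library were drawn separately. A change of 2 on the log2 scale was recovered for 23.4% of genes in T-cell-like nuclei with 7 libraries (16972 genes run) and 49.2% without pair A (17499 genes run); for a change of 4 these were 87.3% and 91.9%. A change of 1 was recovered for 0 of 65 and 1 of 67 genes. False calls numbered 1 with 7 libraries. Without pair A they numbered 10, beside 1, 32 and 57 recovered genes with changes of 1, 2 and 4. With pair A libraries kept, false calls numbered 5 in CD4 and 11 in CD8 T-like nuclei, 6 in NK-like nuclei and 11 for promoters. In pairs B to D they numbered 12 in cluster 9 and 5 in cluster 10. The fits without pair A of CD4, CD8 and NK-like nuclei and of promoters were not simulated. Each comparison was simulated once. Counts of the promoter test recovered 83.6% of changes of 1 (12512 genes run).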

Results

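The data comprised RNA and open-chromatin counts from 19867 nuclei of stimulated myeloma blood mononuclear cells, 4 libraries with DMSO and 3 with mezigdomide. Depth differed widely. Counted in the nuclei kept, the DMSO library of pair A held 188 nuclei and 1811155 UMIs, its mezigdomide partner 1485 nuclei and 14848634 UMIs. Pair B held 4598 and 3961 nuclei with 38613586 and 19423550 UMIs. Pair C held 2898 and 4690 nuclei with 20383634 and 19613775 UMIs, and the DMSO library of pair D 2047 nuclei and 26282110 UMIs. T-cell-like nuclei made up 14104 of the total, B-like nuclei 2080 and NK-like nuclei 907. UMIs in T-cell-like nuclei ran from 1765980 per library to 26972540.

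The first question, which the series title raises, was how mezigdomide changes the RNA of stimulated T cells. With all 7 libraries as labelled, 0 of 17378 genes were called in T-cell-like nuclei by edgeR, 253 had an unadjusted p under 0.05, and DESeq2 and voom also called 0. RNA of the drug's protein targets was not called: IKZF1 (Ikaros, a lymphoid transcription factor; ENSG00000185811, chromosome 7, 50304068 to 50405101 on GRCh38) differed by 0.62 ± 0.47 on the log2 scale (adjusted p = 1.00), and IKZF3 (Aiolos; ENSG00000161405, chromosome 17, 39757715 to 39864188) by 0.41 ± 0.39. IKZF2 (Helios) differed by 0.50 ± 0.55, ZFP91, another target of such drugs, by 0.03 ± 0.25, and CRBN, which encodes cereblon, by 0.28 ± 0.25. Protein was not measured. For genes with large differences, the libraries of pair A lay opposite to the others. TNC (tenascin C, an extracellular matrix protein; ENSG00000041982, chromosome 9, 115019578 to 115118257) stood at 703 CPM in the library labelled DMSO of pair A, against 1.57 ± 0.462 CPM in the other 3 DMSO libraries. With the label number as a block, 0 genes were called as well.

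Without pair A, a comparison chosen after its values were seen, 133 of 17857 genes were called in T-cell-like nuclei, 127 higher and 6 lower with mezigdomide, from 3 DMSO and 2 mezigdomide libraries. TNC rose by 8.98 ± 0.56 on the log2 scale, from 1.57 ± 0.462 to 810 ± 457 CPM (adjusted p = 0.0172). INHBA, which encodes the activin A subunit (ENSG00000122641, chromosome 7, 41667168 to 41705834), stood at 0.0614 ± 0.0604 CPM with DMSO and 413 ± 340 CPM with mezigdomide. It is among the leading genes of a CD8 cluster but was not confined to CD8 nuclei. Its counts with mezigdomide were 9607 in CD4 T-like, 2942 in CD8 T-like and 234 in NK-like nuclei, against 3, 1 and 1 with DMSO. TMEM132A rose from 0.371 to 38.9 CPM, the adhesion adaptor PARVA from 0.133 to 11.8 CPM and the tetraspanin TSPAN18 from 1.06 to 19.9 CPM. The TNF-inducible TNFAIP2 rose by 5.83 ± 0.46, from 0.703 to 39.4 CPM. It is a leading gene of B-like cluster 9 and stood at 1720 and 2041 CPM in clusters 9 and 10 with mezigdomide; RNA carried over from such nuclei was not separated. CSF2RA, the GM-CSF receptor alpha chain, rose by 5.12 ± 0.41. The cadherin CDH13 rose by 5.98 ± 0.47, the membrane protein EMP2 by 6.08 ± 0.51, and the secreted C1QTNF1 from 0.0459 to 5.69 CPM. The survival gene BIRC3 rose by 1.73 ± 0.23, from 172 ± 24.7 to 572 ± 24.7 CPM (adjusted p = 0.0398).

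The 6 genes that fell included TIGIT, an inhibitory receptor of T and NK cells (ENSG00000181847, chromosome 3, 114276913 to 114310288), which went from 43.4 ± 6.58 to 9.77 ± 1.48 CPM, a log2 change of -2.16 ± 0.28 (adjusted p = 0.0386). The calcium sensor NCS1 changed by -3.09 ± 0.39, the hormone-responsive GREB1 by -3.53 ± 0.45, the transporter SLC16A9 by -3.06 ± 0.41 and the interleukin-1 receptor subunit IL1RAP by -1.57 ± 0.22. The B-cell gene MS4A1 changed by -3.25 ± 0.44 in these T-cell-like sums, from 3.05 to 0.318 CPM. MS4A1 also fell in the B-like clusters, from 251 ± 37.0 to 99.3 ± 56.1 CPM in cluster 9 and from 119 ± 53.1 to 5.95 ± 8.41 CPM in cluster 10, and RNA carried over from such nuclei was not separated. With the label number as a block, in pairs B and C, the next lower genes were HILPDA, RYR1, ADCY1 and RASGRP4 (adjusted p there = 0.00120, 0.00153, 0.00153 and 0.00167), which were not called without the block; RYR1 is a leading gene of a CD4 cluster. HILPDA, a lipid droplet gene of hypoxia, stood at 66.6 ± 40.1 and 10.1 ± 7.11 CPM. IKZF1 stood at 375 ± 95.4 and 862 ± 158 CPM, which was not called by edgeR without the block (adjusted p = 0.149), and was called higher with the block (0.00821) and by DESeq2 (0.00721); over the other settings it ran to 0.441. All 133 genes kept their sign in each fit that left out a further library, but in the fit without a block the calls did not stand: 0 genes were called without the DMSO library of pair C, 0 without that of pair D, 1 without that of pair B, and 58 without the mezigdomide library of pair C. Leaving out pair B or pair C instead of pair A gave 0 genes each (121 and 57 at an unadjusted p under 0.05), so the calls rest on the choice to leave out pair A. With the label number as a block 1371 genes were called in pairs B and C, among them 132 of the 133. On the same 4 libraries 0 were called without the block. The block fit leaves few degrees of freedom for the spread, so its tests lean on spread shared across genes. In pairs B to D DESeq2 called 1198 and a test without the low-count filter 437.

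**Figure D1:**
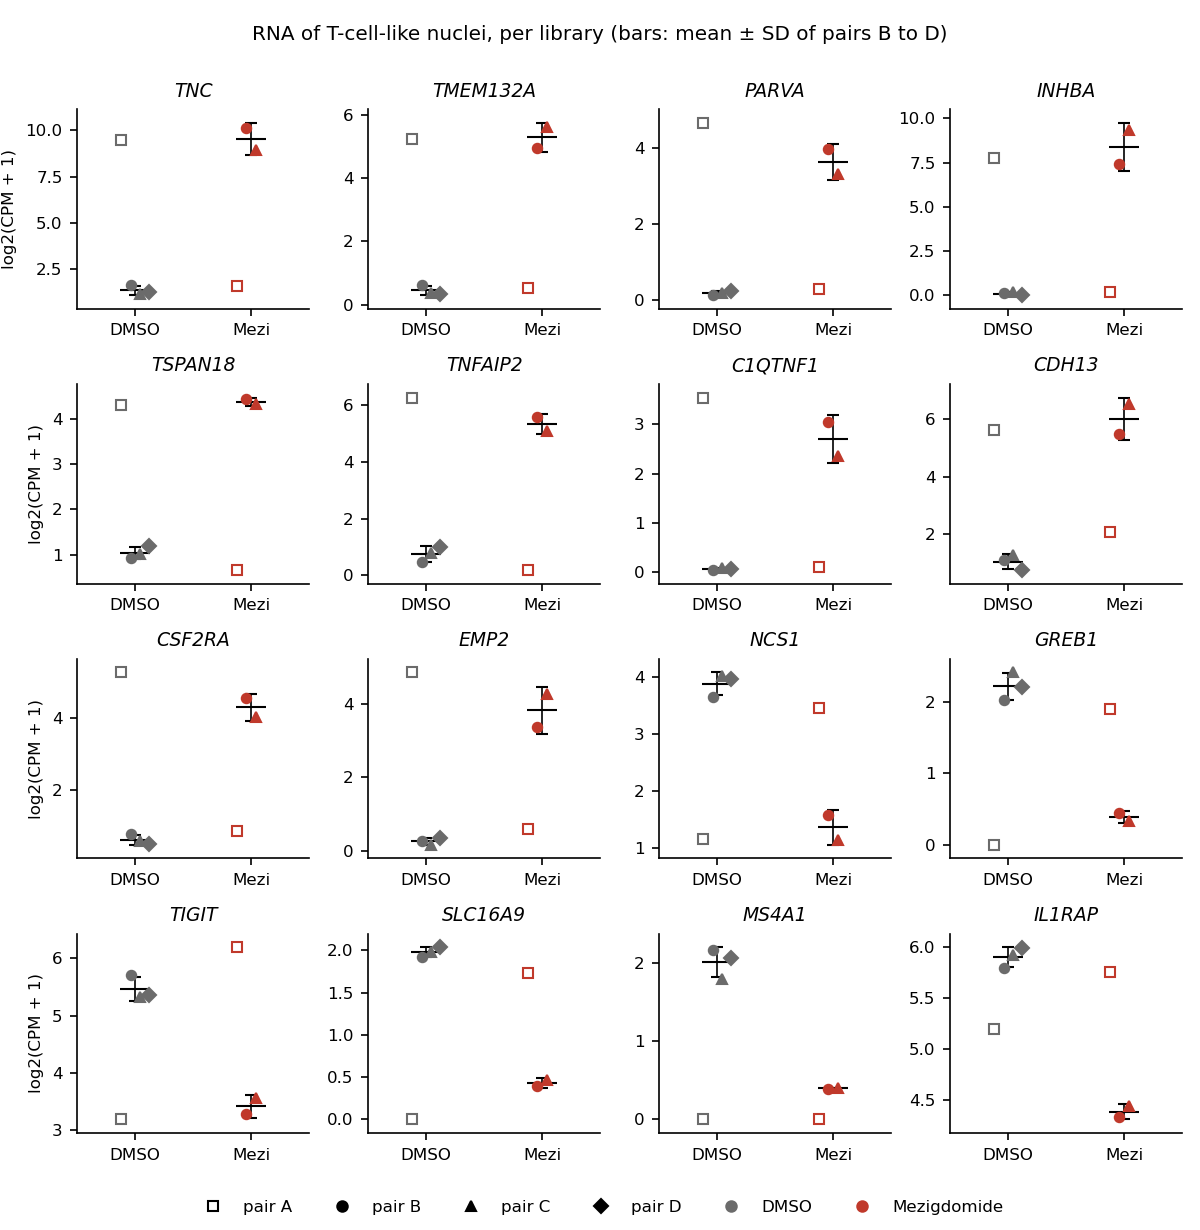
RNA levels of 16 genes in T-cell-like nuclei as log2(CPM + 1), 1 panel per gene, with DMSO (grey) and mezigdomide (red) libraries as points and the mean ± SD of pairs B to D as bars; open squares are pair A. For TNC the open DMSO square, at 703 CPM, lies with the mezigdomide libraries of pairs B and C, which average 810 CPM.

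Gene lists gave a broader view of the same nuclei. As labelled, 9 of 29 lists were called by camera, 4 higher and 5 lower with mezigdomide, while with an estimated correlation and with fry 0 were called. Interferon-stimulated genes were higher (27 of 28 positive, median 0.64, adjusted p = 0.844 with an estimated correlation), led by XAF1 at 1.76 ± 0.95. Such genes (IFIT2, IFIT3, RSAD2) lead CD4 cluster 7, whose nuclei were spread unevenly. With DMSO and mezigdomide it held 3 and 191 nuclei in pair A, 656 and 43 in pair B and 11 and 15 in pair C. MHC class II genes (7 of 10 positive, adjusted p = 0.844 with an estimated correlation), chemokine receptors (13 of 18 positive, 0.844 likewise) and the dendritic list, of which 1 gene, LAMP3, was measured (0.672 likewise), were also called higher. Proliferation genes were lower (30 of 30 negative, median -0.27; adjusted p = 0.844 with an estimated correlation), as were MYC and ribosome biogenesis genes (19 of 19, median -0.44), sterol synthesis genes (13 of 16) and ribosomal protein genes (20 of 22), each with 0.844 likewise. The B-cell markers were lower too (8 of 9 negative, median -1.25, 0.672 likewise), and 3 of them passed when adjusted over the list alone, the only list with members that did. MS4A1 had 0 counts in both libraries of pair A, where B-like nuclei made up 0.532% and 0.404%. It had 41 to 110 counts in the other DMSO libraries (4.97% to 20.5%), and 6 and 5 with mezigdomide in pairs B and C (15.4% and 4.95%). RNA carried over from B-like nuclei may enter these sums and was not separated, here or without pair A.

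Without the block the other 20 lists were not called, and none of their members passed over all genes or adjusted over the list alone. Members with positive differences numbered 9 of 14 in the Ikaros and cereblon list, 11 of 20 in exhaustion, 11 of 28 in effector cytokines, 5 of 7 in Th2, 3 of 10 in Th1, 5 of 9 in Th17 and 5 of 11 in regulatory T. They numbered 13 of 16 in cytotoxic genes, 10 of 15 in naive and memory genes, 8 of 16 in costimulation, 13 of 24 in T-cell receptor signalling, 9 of 15 in IL-2 and STAT5 and 10 of 18 in AP-1 and NF-kB genes. In glycolysis they were 5 of 17, in apoptosis and survival 13 of 18, in monocyte markers 2 of 5, in plasma cell markers 2 of 5, in NK markers 3 of 6, in heat shock 3 of 17 and in mitochondrial transcripts 3 of 13. For 7 of these lists the test pointed against the median: effector cytokines, regulatory T, costimulation and monocyte markers had negative medians and pointed up, and Th2, Th17 and T-cell receptor signalling had positive medians and pointed down. With the label number as a block 7 lists were called: exhaustion (adjusted p = 0.0129) and cytotoxic genes (0.00772) were gained, both higher (0.957 and 0.952 with an estimated correlation, without the block), and sterol synthesis (0.0731), chemokine receptors (0.0613), B-cell markers (0.0673) and the dendritic list (0.178) were lost. Of the exhaustion genes TOX had the smallest p, at 0.93 ± 0.55.

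Without pair A, camera called 11 lists, 4 higher (interferon-stimulated, MHC class II, chemokine receptors, monocyte markers) and 7 lower (proliferation, MYC and ribosome biogenesis, glycolysis, sterol synthesis, B-cell markers, heat shock, ribosomal proteins), and 0 of them with an estimated correlation (smallest adjusted p = 0.713). With the label number as a block, in pairs B and C, these 11 were called and 7 more: exhaustion (adjusted p = 0.0118), effector cytokines (0.00635), cytotoxic (0.000202), naive and memory (0.0118), T-cell receptor signalling (0.0473) and IL-2 and STAT5 genes (0.0120) higher, and Th2 lower (0.0120), none of them with an estimated correlation without the block (smallest adjusted p = 0.713). All 30 proliferation genes were negative (median -0.99), and 19 of them passed when adjusted over the list alone, though none over all genes. MKI67, a marker of cycling cells, stood at 256 ± 51.2 and 93.6 ± 21.5 CPM (adjusted p = 0.0831) and RRM2 differed by -1.23 ± 0.26. All 19 MYC and ribosome biogenesis genes were negative. Of 20 exhaustion genes, TIGIT was called lower and 14 were positive, among them PRDM1 at 1.64 ± 0.35 (adjusted p = 0.111); adjusted over the list alone, 1 passed higher and 1 lower. Among 28 effector cytokines none was called, and 5 passed higher and 3 lower when adjusted over the list alone. IL3 stood at 4.76 ± 1.81 and 280 ± 319 CPM (adjusted p = 0.0567), TNFSF14 at 51.6 ± 2.95 and 15.9 ± 5.24 CPM, and IL17F, of the Th17 list, at 351 ± 311 and 14.8 ± 3.44 CPM; IL3 and IL17F are leading genes of a CD4 cluster. Interleukin 10 (IL10) differed by 3.75 ± 0.75 (adjusted p = 0.0901).

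CD4 and CD8 T-like nuclei were compared on their own. As labelled, edgeR called 0 of 15877 genes in CD4 (181 at an unadjusted p under 0.05; 0 by DESeq2) and 0 of 11477 in CD8 (320 at an unadjusted p under 0.05; 2 by DESeq2; 8 without the mezigdomide library of pair A). Without pair A, 186 genes were called in CD4 (175 higher) and 100 in CD8 (96 higher), of which 105 and 52 were also among the T-cell-like calls. In CD4 nuclei TMEM132A, PARVA, LINC01283, TNC and HSD11B1, a glucocorticoid-activating enzyme, led the higher genes; HSD11B1 went from 10.8 ± 1.33 to 126 ± 29.7 CPM. TIGIT changed by -2.62 ± 0.25, the T-cell adhesion molecule CRTAM by -4.33 ± 0.56, and ASB2, NCS1 and SLC16A9 were lower too. In CD8 nuclei CDH13, IL6R (interleukin-6 receptor), INHBA, TMEM132A and TNC led, with IL6R rising from 5.44 ± 1.65 to 94.2 ± 1.42 CPM. The 4 lower genes there were RBM47, SSBP4, NCS1 and LIF, a cytokine of the interleukin-6 family, which changed by -4.89 ± 0.75. The clusters that make up these classes differed between groups: in pair C, CD8 cluster 13 held 4 DMSO and 549 mezigdomide nuclei and cluster 14 held 468 and 25, and in pair B, CD4 cluster 7 held 656 and 43. In CD4 the count was 0 without the DMSO library of pair C or of pair D and 54 without that of pair B. In CD8 it was 2, 4 and 7 without the DMSO libraries of pairs D, C and B, and 54 without the mezigdomide library of pair C. With all 7 libraries as labelled, the difference of effect between CD8 and CD4 was called for 0 of 15324 genes by edgeR (512 at an unadjusted p under 0.05). So no difference between them was shown. With the label number as a block crossed with class 7 were called, and without pair A 2. In simulated data this test recovered 0 of 67 changes of 1 and 10 of 67 changes of 2 on the log2 scale. Those data drew the CD4 and CD8 sums of a library separately, so they held no spread shared by both sums. In the real test the block can take up such spread, so these rates may not be those of the real test. Differences may have been missed.

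Shares of nuclei did not pass a test for any of 7 classes, and with 4 against 3 libraries none could. CD4 T-like nuclei made up 38.0 ± 15.5% with DMSO and 38.6 ± 20.4% with mezigdomide (SD, n = 4 and 3; exact permutation p = 0.914). CD8 T-like nuclei made up 18.5 ± 12.6% and 12.7 ± 4.79%, NK-like nuclei 3.40 ± 1.34% and 5.52 ± 1.98% (exact permutation p = 0.286; within pairs A, B and C the differences were 0.324, 1.58 and 3.01 points, the first with its labels as given), regulatory T-like nuclei 0.811% and 1.16% on average, and B-like nuclei 8.25 ± 8.61% and 6.93 ± 7.70%. T nuclei not resolved into CD4 or CD8 were 14.7 ± 5.85% and 23.3 ± 18.3%, and unnamed nuclei 16.3 ± 6.99% and 11.8 ± 7.87%. Without pair A the means were 3.12% and 6.0% for NK-like, 33.3% and 35.8% for CD4, 20.4% and 11.6% for CD8, 12.2% and 27.8% for unresolved T, 0.904% and 1.10% for regulatory T, 10.8% and 10.2% for B-like and 19.3% and 7.59% for unnamed nuclei. Clusters differed between groups within a class: cluster 2, of unresolved T nuclei, held 1387 nuclei in the mezigdomide library of pair C and 9 in its DMSO partner.

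**Figure D2:**
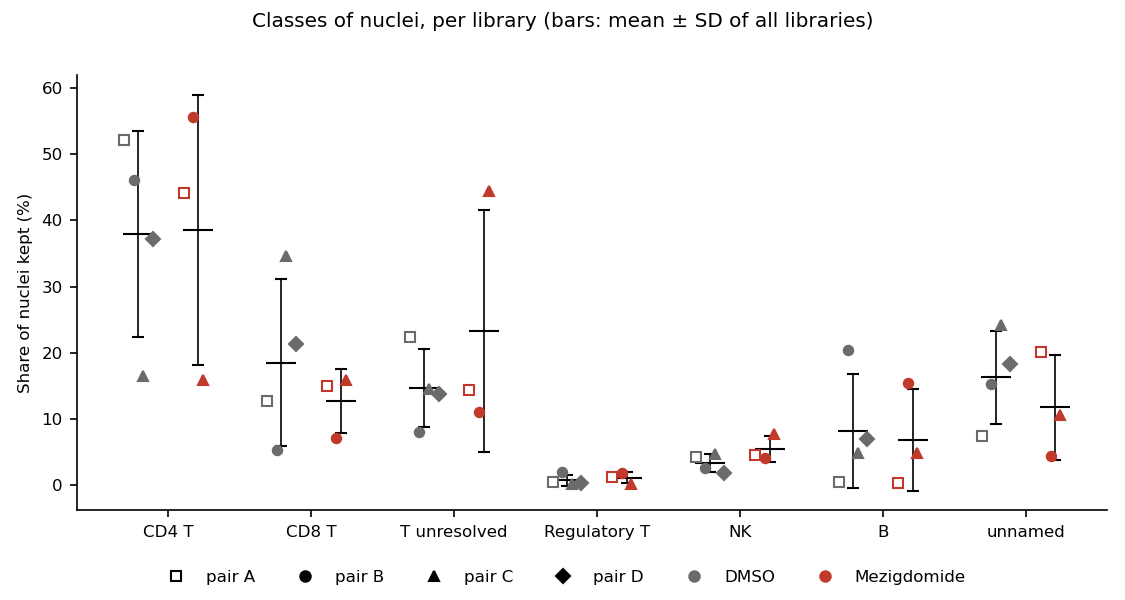
Share of the nuclei kept in each library, in percent, by class, with points for libraries (grey DMSO, red mezigdomide, open squares pair A) and bars for the mean ± SD of all libraries. CD4 T-like nuclei average 38.0% with DMSO and 38.6% with mezigdomide, with wide overlap.

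Promoter peak counts were tested over all kept nuclei. Peaks were called in each library on its own, 22319 to 123747 of them over 19.5 to 106 Mb, so a sum over peaks also moves with how much was called. As labelled, edgeR called 0 of 12512 genes (447 at an unadjusted p under 0.05; 0 with the label number as a block). In the fits without pair A the tested promoters still needed a peak in all 7 libraries, also with shared peaks. In the DMSO library of pair A 12678 genes had a promoter peak, against 19555 to 20609 in the 5 compared libraries. Promoters without a peak in pair A therefore stayed untested. Without pair A, where each library covered 91.7 to 106 Mb, 353 promoters were called, 268 with higher and 85 with lower counts with mezigdomide. Their calls depend on peak calling, as settings added after they were seen show. Taken per covered length, 388 promoters were called, but only 111 of the 353 were among them, 97 higher and 14 lower. With only peaks shared by all 5 libraries 481 were called, 268 of the 353 among them, and with both changes 496, with 243 of the 353. Of the 10 named promoters, 4 were called under all of these. Counts rose at RUSC1 by 2.43 ± 0.16 and per covered length by 1.44 ± 0.17, where the covered length was 0.897 kb with DMSO and 1.78 kb with mezigdomide and the mean value 17.6 and 47.8 CPM per kb. At RIC8B they rose by 0.92 ± 0.07 and per length by 0.91 ± 0.08 (0.892 and 0.894 kb, 66.1 ± 3.00 and 124 ± 6.06 CPM per kb). At GCDH they changed by -0.82 ± 0.07 both ways (0.908 and 0.914 kb, 102 ± 0.662 and 57.6 ± 0.958 CPM per kb). At IL6R-AS1, an antisense gene whose window overlaps that of IL6R, they rose by 1.17 ± 0.09 and per length by 0.70 ± 0.09 (1.75 and 2.43 kb, 30.1 ± 2.22 and 48.6 ± 0.251 CPM per kb). IL6R itself was called with shared peaks, at 0.85 ± 0.09, and with both changes, at 0.85 ± 0.08 (adjusted p = 0.00652), the same values as IL6R-AS1. It was not called per covered length over all its peaks (adjusted p = 0.134, 2.31 and 2.85 kb, 26.1 ± 5.38 and 44.2 ± 5.99 CPM per kb). The lower sum at MYB, -1.63 ± 0.08, went with a covered length of 2.19 and 0.874 kb. It was called with shared peaks but not per length (adjusted p = 0.298, 58.1 ± 7.60 and 46.4 ± 0.414 CPM per kb) or with both changes (adjusted p = 0.156). ARF3, RNF44, ZNF140 and HLA-DMA were called under none of these settings. Of 54 genes with higher RNA in T-cell-like nuclei and a tested promoter, 44 had a positive difference per covered length and 5 were called, against 47 and 13 for the plain sums; over all 11027 genes compared, 49.0% and 48.8% of differences were positive. The RNA came from T-cell-like nuclei and the promoter counts from all kept nuclei of the same libraries. A different mix of B-like, NK-like and unnamed nuclei can therefore enter the promoter counts. For the plain sums, 0 promoters were called without the DMSO library of pair D, 65 without that of pair C and 94 without that of pair B.

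B-like nuclei of clusters 9 and 10 were compared after the data were seen, in pairs B to D, since pair A had too few. Both clusters were named from B-cell markers; among the leading genes of cluster 9 are also IDO1, CCL17, CXCL9 and LAMP3, which mature dendritic cells express, and among those of cluster 10 CCL22 and KYNU, which dendritic or myeloid cells express, beside the B-cell factor EBF1. In both clusters genes of the cell cycle were lower with mezigdomide. In cluster 9, 1822 of 9541 genes were called, 1008 higher and 814 lower. MKI67 changed by -4.42 ± 0.46, from 208 ± 50.7 to 9.29 ± 5.48 CPM (n = 3 and 2), TOP2A, a topoisomerase of dividing cells, by -3.71 ± 0.39, DTL, a ubiquitin ligase subunit that acts in S phase, by -5.19 ± 0.44, and the DNA repair genes POLQ and BRCA1 by -5.92 ± 0.61 and -3.49 ± 0.37. ATAD2, HELLS, RRM2, CENPK and ASPM fell as well. In cluster 10, 895 of 9544 genes were called, 444 higher and 451 lower, with 24 nuclei in its mezigdomide library of pair C. DIAPH3 went from 372 ± 111 to 1.32 ± 1.87 CPM, POLQ from 262 ± 34.9 to 5.65 ± 4.25, and KIF14, DTL, ASPM, CIT, FANCI and GTSE1 fell; BUB1 and KIF4A, at 79.3 ± 16.7 and 71.3 ± 4.09 CPM with DMSO, had no counts with mezigdomide. Of 30 proliferation genes 29 were called lower in cluster 9 and 28 in cluster 10 (median -2.97 and -3.11). Their adjusted p was 0.221 and 0.285 with an estimated correlation, and 0.0108 and 0.0249 by fry. Markers of cell identity moved in the same nuclei. The B-cell marker MS4A1 changed by -1.33 ± 0.38 in cluster 9 and -3.63 ± 0.63 in cluster 10. LAMP3, the only measured member of the dendritic list, rose from 57.7 ± 45.8 to 459 ± 82.5 CPM and from 3.08 ± 2.43 to 109 ± 55.7 CPM. The monocyte marker CTSB rose by 1.70 ± 0.45 and 1.56 ± 0.46. The B-cell list was not called (adjusted p = 0.303 and 0.460), and PAX5 stood at 353 ± 69.4 and 628 ± 31.4 CPM in cluster 10 (adjusted p = 0.170).

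Among the higher genes of cluster 9 were PVR, the ligand of TIGIT (10.8 ± 2.64 to 223 ± 88.1 CPM), the inhibitory ligand CD200 (28.1 ± 12.6 to 418 ± 31.5 CPM), TMCC2, MPZL1, NUAK2, MYO1E and ZFP36, which promotes mRNA decay. In cluster 10 they were TNFAIP2 (45.5 ± 18.8 to 2041 ± 356 CPM), FLT3, a receptor kinase that dendritic cells and their precursors express (3.23 ± 1.38 to 109 ± 19.6 CPM), PVR, PSD3, UPB1, ATXN7L1, NUAK2, LINC02541, RNF19B and MOXD1. AP-1 and NF-kB genes were called higher as a list in both, with 6 of 15 members called higher in cluster 9, and 3 higher and 1 lower in cluster 10, such as RELB at 1.75 ± 0.28 and 1.79 ± 0.33 and TNFAIP3 at 2.41 ± 0.39 and 1.90 ± 0.41 (list adjusted p = 0.517 and 0.586 with an estimated correlation). IKZF1 RNA rose in cluster 9, by 1.47 ± 0.33 (adjusted p = 0.0117), and differed by 0.78 ± 0.35 in cluster 10 (adjusted p = 0.188). Of 19 MYC and ribosome biogenesis genes 15 were called lower in cluster 9 and 5 in cluster 10 (list adjusted p = 0.517 and 0.586 with an estimated correlation), NCL by -2.22 ± 0.41 and -1.84 ± 0.45. The plasma cell gene MZB1 fell in both, from 78.3 ± 33.0 to 3.83 ± 2.86 CPM in cluster 9. Calls shared by the clusters numbered 338 higher and 360 lower, against 42.4 and 37.5 for independent lists, with 0 in opposite directions; both clusters come from the same libraries. In cluster 9 the count was 978 without the DMSO library of pair C, 1008 without that of pair D, 1036 and 1064 without the mezigdomide libraries of pairs B and C, and 2675 without the DMSO library of pair B. In cluster 10 it was 105 without the mezigdomide library of pair B, 540 without the DMSO library of pair D and 1648 without that of pair B.

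**Figure D3:**
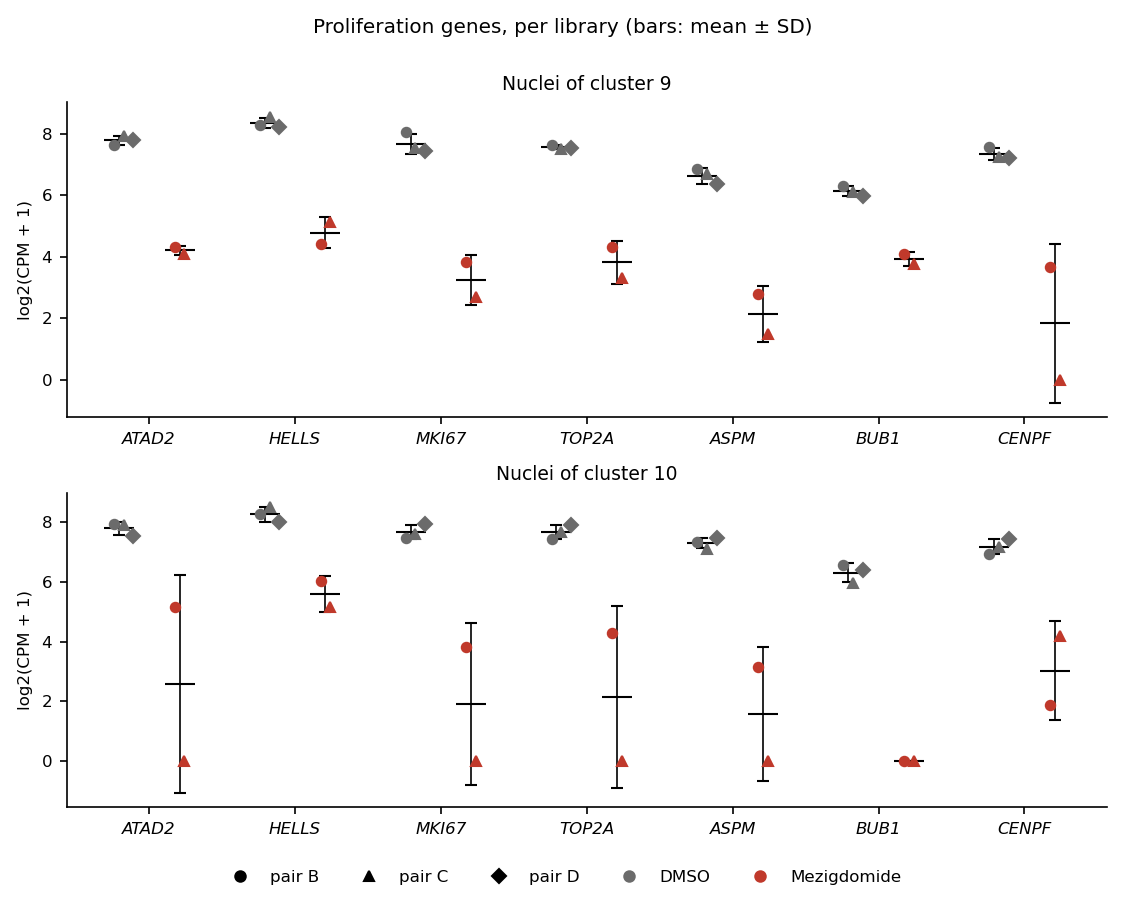
Levels of 7 proliferation genes as log2(CPM + 1) in nuclei of clusters 9 (top) and 10 (bottom), with points for the libraries of pairs B, C and D (grey DMSO, red mezigdomide) and bars for the mean ± SD. Every mezigdomide point lies below every DMSO point of its gene, and for MKI67 in cluster 9 the means are 208 and 9.29 CPM.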

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

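All tests of explanations in this part, and the fits without pair A and of clusters 9 and 10 that they rest on, were chosen after the result was seen.

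Within the 4 DMSO libraries, the gap of the most distant library to its nearest neighbour was compared with the range of the group. Of 33 measures (25 genes in T-cell-like nuclei and 8 shares), 12 had a library far from the others; chance gives about 1 in 20 groups. For 11 genes it was the library labelled DMSO of pair A. The gap as a share of the range was 0.9987 for TNC, 0.9994 for INHBA, 0.9928 for TMEM132A, 0.9964 for PARVA, 0.9782 for TSPAN18, 0.9917 for TNFAIP2, 0.9973 for C1QTNF1, 0.9853 for CDH13, 0.9923 for CSF2RA, 0.9946 for EMP2 and 0.8993 for SLC16A9. These genes were named for their difference in the other pairs, so they are not independent measures. The share of regulatory T-like nuclei in the DMSO library of pair B gave 0.8553.

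Pair A ran against the other pairs. Across 8209 genes of T-cell-like nuclei its difference correlated with the fit of the other pairs at -0.7551, while pairs B and C correlated with each other at 0.678; this difference between pairs was not tested. Of the 133 genes called without pair A, 132 were opposite in it.

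Exchanged labels of the pair A libraries may explain this pattern: for 86.5% of the 133 genes each of these libraries lay nearer the mean of the other group. Few nuclei in the DMSO library were not excluded. With the same number of nuclei in every library the correlation was -0.681. That number was set by this library, whose 165 T-cell-like nuclei stayed the same, so the test cannot decide. Pairs B and C, cut to that number, still correlated with each other at 0.545, so few nuclei did not reverse those pairs. An opposite response from a common vehicle level is argued against. On a scale with the DMSO mean at 0 and the mezigdomide mean at 1, the library labelled DMSO had a median position of 1.05. A treated-like state of this donor that the drug removed cannot be told apart from exchanged labels, because both put the library labelled mezigdomide near 0 (0.0237). Labels were kept as given.

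Treatment effects differed between cluster 10 and T-cell-like nuclei for 857 of 17685 genes, 194 more raised and 663 more lowered in cluster 10. The difference was tested as an interaction. Leading genes were DIAPH3 at -7.26 ± 0.51 and POLQ at -6.03 ± 0.50 in one direction, S100A10 at 2.32 ± 0.27 and CD82 at 2.07 ± 0.27 in the other. The balance of directions depends on scaling. The median over all genes was -0.26 here and -0.12 with RLE scaling, which called 787 genes, 270 raised and 517 lowered. The label number as a block gave 248 and 394. Without the mezigdomide library of pair B the count was 393, 98 and 295, with a median of -1.31.

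Lower proliferation genes in clusters 9 and 10 were weighed against technical explanations. Lower depth of the mezigdomide sums is argued against: with every sum of cluster 10 thinned to the smallest, 21 of 25 measured genes were still called lower. A drop of the same size in all nuclei of a library is argued against by 26 of 30 genes that were more lowered in cluster 10 than in T-cell-like nuclei. A different mix of B-like clusters is argued against, since within a cluster at least 28 of 30 genes were called lower. A different mix of cells inside each cluster was not tested and stays open. The libraries were aligned before clustering, which can bring unlike nuclei of the groups into the same cluster. Identity markers moved along in clusters 9 and 10: MS4A1 changed by -1.33 ± 0.38 and -3.63 ± 0.63, and the dendritic marker LAMP3 by 2.98 ± 0.51 and 5.03 ± 0.59, while FLT3 rose from 3.23 to 109 CPM in cluster 10. No biological explanation was tested.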

How the results depend on the processing

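The fits without pair A, in pairs B to D and in clusters 9 and 10 were chosen after seeing the data, as were all their settings. So was the difference between cluster 10 and T-cell-like nuclei. Of the settings as labelled, those without pair B, without pair C and without the unresolved T clusters were also chosen then. The same holds for the promoter settings that take account of peak calling. The other settings were chosen before. The cause of a change was not tested unless stated.

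As labelled, T-cell-like and CD4 nuclei gave 0 genes by edgeR (253 and 181 at an unadjusted p under 0.05; 0 by DESeq2) under every setting run except without pair A, with 133 and 186. In CD8 nuclei DESeq2 called 2 genes, the fit without pair A 100, and fits without 1 library 0 to 8, with 8 without the mezigdomide library of pair A. Promoters gave 353 without pair A and 0 to 2 without 1 library, with 2 without the mezigdomide library of pair C. The difference between CD8 and CD4 gave 7 genes with the label number as a block crossed with class, 33 without the low-count filter, 2 without pair A and 0 to 4 without 1 library, with 4 without the mezigdomide library of pair B and 1 each without the libraries of pair C.

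In pairs B to D, the block, no low-count filter and DESeq2 gave 1371, 437 and 1198 genes in T-cell-like nuclei, 1169, 606 and 909 in CD4, and 534, 1194 and 620 in CD8. Promoters gave 666 with the block and 1100 by DESeq2. With settings added after the promoter calls were seen, they gave 388 per covered length, 481 with peaks shared by the compared libraries and 496 with both, and 111, 268 and 243 of the 353 were called again in the same direction. As labelled each of these gave 0. The block drops the DMSO library of pair D, which has no partner here. It leaves few degrees of freedom for the spread in pairs B and C, so its calls lean on spread shared across genes. Of the 133 genes in T-cell-like nuclei, 132 were also called with the block and 133 by DESeq2.

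Counts without 1 library in pairs B to D ran from 0 to 116 in T-cell-like nuclei, 0 to 160 in CD4, 2 to 137 in CD8 and 0 to 331 for promoters. In T-cell-like nuclei they were 0 without the DMSO library of pair C or D, 1 without that of pair B and 58 without the mezigdomide library of pair C. In CD4 they were 0 without the DMSO library of pair C or D and 54 without that of pair B. In CD8 they were 2, 4 and 7 without the DMSO libraries of pairs D, C and B and 54 without the mezigdomide library of pair C. For promoters they were 0, 65 and 94 without the DMSO libraries of pairs D, C and B. Where 1 mezigdomide library was left, it was assumed to vary like the others.

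Cluster 10 gave 1486 genes with the label number as a block, and all B-like nuclei together gave 1895. That sum adds clusters 16 and 25, which in the DMSO libraries of pairs B, C and D held 386, 16 and 8 nuclei and 68, 5 and 4, and in the mezigdomide libraries of pairs B and C 1 and 1 and 0 and 0, so it compares different mixes of clusters. Without 1 library, cluster 10 gave 105 (mezigdomide of pair B) to 1648 (DMSO of pair B), with 540 without DMSO of pair D. Cluster 9 gave 978 (DMSO of pair C) to 2675 (DMSO of pair B), with 1008 without DMSO of pair D and 1036 and 1064 without mezigdomide of pairs B and C. The difference between cluster 10 and T-cell-like nuclei gave 393 (without mezigdomide of pair B) to 847.

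Of 9 gene lists called as labelled, 0 were called with an estimated correlation, 0 by fry and 5 with equal numbers of nuclei. The label number as a block gave 7, of which exhaustion and cytotoxic genes were not among the 9, and 4 of the 9 were not called. Without 1 library 5 to 10 were called, with 5 without the mezigdomide library of pair C and 6 without the DMSO library of pair B.

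Differences in share, none of which passed a test, changed sign in 14 of 84 values. In percentage points, CD4 was -1.89 with doublets kept, -1.70 with at least 1000 UMIs, -1.77 with at most 10% mitochondrial UMIs and -1.95 at Leiden resolution 0.5; CD8 was 3.50 with at least 1000 UMIs and 2.39 with the mitochondrial limit, under which B was 1.11. Without 1 library CD4 ran from -7.92 to 11.9, B from -5.57 to 2.76, unresolved T from -1.93 to 14.7 and regulatory T from -0.0325 to 0.788.

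Single genes that reversed were not called to begin with. On the log2 scale as labelled, ZFP91 was -0.054 with the block, -0.15 with equal nuclei and -0.087 to 0.16 without 1 library. IL5 was -1.60 with the block, -2.68 by voom, -0.16 with equal nuclei, -3.23 without pair A and -2.88 to 2.62 without 1 library. XAF1 and TYROBP were -0.12 and -0.12 without pair C, and without 1 library TYROBP ran from -0.85 to 1.68 and FGFBP2 from -0.23 to 2.89. In pairs B to D, ZFP91 was -0.079 with the block, -0.0089 without the low-count filter, -0.0265 with equal nuclei and -0.20 to 0.25 without 1 library, where GNLY ran from -0.88 to 3.05, FGFBP2 from -3.41 to 3.93, CD38 from -0.17 to 2.47 and FCER1G from -0.15 to 1.97. In cluster 9, IL9 ran from -0.14 to 3.32, GZMA from -1.12 to 2.88 and CIITA from -0.33 to 1.01, and in cluster 10 IL9 from -7.65 to 2.85.

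Of 857 values of 78 named genes in T-cell-like nuclei of pairs B to D, 678 kept direction and side of the threshold, 81 passed it only under the other setting, 88 no longer passed and 10 reversed. In cluster 9 these were 615, 14, 63 and 3 of 695, and in cluster 10 585, 35, 84 and 1 of 705. What depth limits was tried in cluster 10: with every sum thinned to the smallest, 3578 genes passed the filter instead of 9544 and 429 were called instead of 895.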

Other observations

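All tests in this part count how often other splits of the same libraries give as many calls, and they were chosen after the results were seen.

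For gene lists in T-cell-like nuclei 20 of 35 splits gave at least the real count of 9, and the highest other gave 14, so chance is not excluded. Of the 8 splits that part as many pairs as the real one, 4 gave at least 9.

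For genes the count of splits says nothing about chance, because the real split called 0 and every split gives at least that: 35 of 35 in T-cell-like, CD4 and CD8 nuclei, for the difference between CD8 and CD4, and for promoters. The highest other splits gave 686, 611, 372, 22 and 640 genes. Splits that call 372 to 686 genes where the real one calls 0 point to a structure of the samples; in T-cell-like, CD4 and CD8 nuclei and for promoters the highest was the split that exchanges the labels of pair A.

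For clusters 9 and 10, 3 against 2 libraries make 10 splits, too few for a share under 0.05. The real split gave 1822 genes in cluster 9 and 895 in cluster 10, and the highest other gave 0 in each, so 1 of 10 splits was as large.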
